A study of Mus musculus with 2 samples.

How the data were processed

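The data are UMI counts of single cells of the 63.3 mouse leukemia line, barcoded per culture with MULTI-seq, pooled and profiled with 10x Genomics v3 chemistry, per the labels' protocols. The authors deposited raw counts of UMIs per cell barcode and gene as a spliced and an unspliced matrix, unfiltered and with both runs in 1 matrix each. The submitters' processing notes name kallisto 0.46, bustools 0.39.4 and Cell Ranger without a role for each. Genome build and annotation are not given in the sources used here. Genes carry versioned Ensembl mouse IDs, of which 54723 of 54838 were given a symbol from a reference table of gene names, 53861 with the version included, and IDs that share a symbol were summed. A deposited table gives each of 10 barcodes its treatment and time, and a deposited annotation by the authors gives the barcode call of 15582 distinct cell barcodes. Of these, 26 were listed more than once, all called negative and so left out. Barcodes carry no mark of the run, so a barcode that occurs in both runs would count as 1 cell. Barcodes called as doublets by the authors (2777, 17.8%) or as negative (265) were left out, and the other 12540 cells were used with no further filter. No doublet caller was run in addition. The cells used held 134068354 of the 209704818 spliced UMIs of all barcodes (63.9%).

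Spliced counts were summed over the cells of each condition and scaled to counts per 1000000 (CPM) of that sum. The unspliced matrix entered only as its total, since no list of barcodes for its lines was used here. The cultures sum to 5236694 to 19931921 UMIs, so a floor of 3 counts stands at 0.151 to 0.573 CPM. Each condition is 1 culture, and the 2 runs repeat 1 pool, so cells and runs are not replicates and no test was run. Each treatment was compared with the 0 h culture of its own series at 6, 12, 24 and 48 h, and brequinar with withdrawal at matched times. A fold is the ratio of CPM, with an exact 95% interval from the conditional binomial distribution (Clopper-Pearson). It covers counting error only.

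The rules for lists and named genes and the main alternatives were set before the data were examined. For each of 27 gene lists, members at 20 CPM or more in either culture count as measured. The number at least 1.5-fold higher or lower is given with the median log2 ratio (pseudocount 5 CPM) and that median's percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these cultures. No measured member had 0 counts in either culture compared. The lists are neutrophil maturation, phagocyte function, primary granule, monocyte macrophage, progenitor, myeloid transcription factor, S phase, G2/M, pyrimidine metabolism, purine synthesis, p53 target, ATF4 and amino acid response, replication stress and repair, ribosome biogenesis, ribosomal protein, interferon response, cholesterol synthesis, glycolysis, oxidative phosphorylation, apoptosis, estrogen receptor target, erythroid, megakaryocyte, mast cell and basophil, eosinophil, dendritic cell and lymphoid. No clusters were made and no cell types assigned.

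Genes named in the text follow a fixed rule. For each treatment at 48 h, among genes at 50 CPM or more in either culture and at least 2-fold different in the same direction at 24 and 48 h, the 10 highest and 10 lowest log2 ratios (pseudocount 5 CPM) were taken. For each treatment at 6 h, and for brequinar against withdrawal at 48 h, the 5 highest and 5 lowest genes at 50 CPM or more in either culture were taken. Mitochondrial genes and predicted or unnamed gene models were left out of both. For each list described the rule set 2 to 4 measured members with the largest ratios in the direction described. The text departs from it in places: some lists have fewer or no examples, or ones not at the very top. Dhodh, Cad, Umps, Itgam, Spi1, Cebpe, Cdkn1a, Esr1, Hoxa9, Meis1, Kit, Cd34, Myc, Mpo, Pcna and Mki67 were always named.

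Cell cycle scores were computed with scanpy on the S phase and G2/M lists, in cells thinned to 2500 UMIs, the largest multiple of 500 that kept at least 80% of the cells of each condition, leaving out shallower cells. A cell was assigned to the S or G2/M class when that score was above 0 and the higher of the 2. It went to the G1-like class when neither score was above 0. Shares carry exact Clopper-Pearson intervals. Lists were then compared within classes on the full counts of the thinned cells. Correlations of the log2 ratios of both treatments were taken across genes at 20 CPM or more in any condition, each treatment against its own 0 h culture, beside 20 simulations in which unchanged cultures were drawn as Poisson counts at the mean rate of the 0 h cultures. Free RNA was profiled in barcodes of 2 to 100 UMIs (1789848 UMIs). The interval of the UMI share of cells with at least 10% mitochondrial UMIs came from 1000 redraws of the cells of each culture and covers no difference between cultures.

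The ratio and list steps were run on simulated data, drawn as independent Poisson counts at the pooled rates and the depths of the real cultures. That is the counting model of the interval. Spread between cells and between cultures was left out, so coverage in real cultures was not tested. For brequinar at 48 h the interval held the known fold for 95.2% of 5595 genes, for withdrawal at 48 h for 95.5% of 5488 and for brequinar at 6 h for 94.4% of 5558. Genes set 2-fold or 4-fold apart were called at least 1.5-fold different in 100% of cases in each of these comparisons, genes set 1.5-fold apart in 48%, 46% and 54%, and genes set 1.25-fold apart or unchanged in 0%. A fold set at the threshold falls on either side of it at any depth, so the values for 1.5-fold measure no loss of sensitivity.

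Alternatives were median-of-ratios scaling, the mean over cells in place of the sum, cells between the 5th and 95th percentile of UMIs, cells under 10% mitochondrial UMIs, members at 100 CPM or more, no minimum beyond 1 count, a pseudocount of 1 CPM, a 2-fold threshold, the other 0 h culture, cells weighted to the 0 h phase shares, unthinned cells, phase boundaries at the 75th percentile of the 0 h cells, cells whose leading phase score exceeds the next by more than 0.1, and correlation over genes at 100 CPM or more. Chosen after seeing the data were the removal of the 2% of cells of each condition richest in S100a8, S100a9, Ngp, Camp, Chil3 and Lcn2 UMIs, the subtraction of 5% of each sum with the free RNA profile, maturation lists in classes bounded at that 75th percentile, median-of-ratios scaling of brequinar against withdrawal, the G2/M median in thinned cells at 24 h of brequinar, and the correlation in cells under 10% mitochondrial UMIs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9 were used.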

Results

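Single-cell RNA was measured in 63.3 cells, a mouse acute myeloid leukemia line kept in medium with beta-estradiol and stem cell factor. Lipid-anchored DNA barcodes marked each culture before the cultures were pooled and loaded for 2 runs, whose cells share 1 matrix. The conditions form 2 series of 5 cultures each. Brequinar at 2 µM was given for 6, 12, 24 or 48 h. Beta-estradiol (0.5 µM in the growth medium) was withdrawn for 6, 12, 24 or 48 h, each series with its own 0 h culture. The labels do not say whether the brequinar 0 h culture received solvent, so its comparisons may hold an effect of solvent as well. Among the conditions there is no untreated culture at 6, 12, 24 or 48 h. Differences from 0 h may thus hold an effect of time in culture or handling at every time. Each of the 10 conditions was 1 culture, so the differences have no replicate check and no test was run. Every interval below is an exact 95% interval that covers counting error only. Cells with a condition numbered 12540, from 528 (brequinar 48 h) to 1536 (brequinar 12 h) per condition. Summed spliced unique molecular identifiers (UMIs) ranged from 5236694 (brequinar 48 h) to 19931921 (brequinar 0 h) per condition. Median UMIs per cell were 14849 and 15229 in the 0 h cultures, 9782 at 48 h of brequinar and 6509 at 48 h of withdrawal. The 0 h cultures lay close together: among 5490 genes at 20 CPM (counts per 1000000) or more in either, 3 were at least 1.5-fold apart, and the SD of the log2 ratio was 0.06. List percentiles were extreme even between these cultures, at 100 for neutrophil maturation (median log2 ratio 0.11, 2 of 11 genes higher) and G2/M (0.04) and at 0.21 for cholesterol synthesis (-0.06). A percentile alone thus marks no effect of treatment, and it is read here beside the median and the members higher or lower. Below, a gene's CPM in the treated culture is set against that in the other culture, followed by the fold and its interval.

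Brequinar inhibits dihydroorotate dehydrogenase, an enzyme of pyrimidine synthesis, and its comparison with 0 h asks which genes differ after the drug. Nucleotides were not measured here. At 48 h genes of maturing myeloid cells were far higher than at 0 h. Hp, which encodes the hemoglobin-binding protein haptoglobin of neutrophil granules, stood at 1713 against 35.2 CPM, 48.6-fold, 45.0 to 52.6. The protease inhibitor gene Stfa1 of the stefin family (3458 against 92.3 CPM, 37.5-fold, 35.7 to 39.3), the neutrophil collagenase gene Mmp8 (116 against 2.76 CPM, 41.9-fold, 31.7 to 56.2) and the myeloid lectin receptor gene Clec4a2 (301 against 8.33 CPM, 36.2-fold, 30.8 to 42.7) were higher as well. Itgam, which encodes the integrin CD11b of mature myeloid cells, had 0 counts at 0 h and 29 at 48 h, at least 36.8-fold higher against a floor of 3 counts in the 0 h culture. With 5% of each sum removed in the profile of free RNA, a setting chosen after seeing the data, the ratios were 86.2-fold for Hp, 197-fold for Stfa1, 73.4-fold for Mmp8 and 106-fold for Clec4a2, all outside the counting intervals. The 5% is a fixed share and not an estimate of free RNA. The size of these folds is thus uncertain beyond the counting intervals.

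Other genes that ranked highest at 48 h of brequinar were Wfdc17, a secreted WAP-domain protein of macrophages (749.5 against 5.87 CPM, 128-fold, 106 to 155), the chemokine gene Ccl3 (812 against 26.99 CPM, 30.1-fold, 27.5 to 33.0), and Thbs1, which encodes thrombospondin (1507 against 95.02 CPM, 15.9-fold, 15.1 to 16.7). Prg2, the major basic protein of eosinophil granules (9165 against 684 CPM, 13.4-fold, 13.1 to 13.7), the costimulatory receptor gene Cd28 (101 against 2.86 CPM, 35.4-fold, 26.9 to 47.4) and Csrp3, which encodes a LIM-domain protein of muscle (142 against 1.15 CPM, 123-fold, 81.2 to 195), completed the highest 10. With the same fixed 5% removed the ratios were 542-fold for Csrp3 and 314-fold for Wfdc17, so the size of these folds is uncertain too. Genes ranked lowest were Aebp1 (2.29 against 58.7 CPM, 25.6-fold lower, 14.6 to 49.7), the chromatin protein gene Hmga2 (16.8 against 132 CPM, 7.88-fold lower, 6.37 to 9.86) and the fatty acid carrier gene Fabp5 (45.1 against 260.4 CPM, 5.78-fold lower, 5.07 to 6.61). Hsph1, a chaperone, was 5.70-fold (4.63 to 7.10) lower, Chchd10, a protein of the mitochondrial intermembrane space, 5.17-fold (4.83 to 5.53) lower, and Ung, which removes uracil from DNA, 4.72-fold (3.79 to 5.94) lower. Ass1, an enzyme of arginine synthesis, was 4.72-fold (4.03 to 5.56) lower, Spns2, a sphingosine-1-phosphate transporter, 4.56-fold (3.51 to 6.03) lower, Mettl1, a tRNA methyltransferase, 4.40-fold (3.73 to 5.22) lower, and Ppid, a cyclophilin, 3.62-fold (3.28 to 4.01) lower. They were taken from the 399 genes at least 2-fold higher and the 118 at least 2-fold lower at both 24 and 48 h.

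Lists of myeloid maturation genes were higher together with brequinar. All 14 measured members of the neutrophil maturation list were at least 1.5-fold higher at 48 h (median log2 ratio 2.78, percentile 100 of 10000 matched random lists), led by Hp, Mmp8, Stfa1 and Wfdc21 (19.3-fold). Of the UMIs of S100a8, S100a9, Ngp, Camp, Chil3 and Lcn2, genes of this list, 66.9% lay in 11 of the 528 cells. Without the 2% of cells richest in them 12 of 13 members were higher (median 2.11). Phagocyte function genes, which encode integrins, Fc receptors and the NADPH oxidase, were higher for 19 of the 22 measured at 24 h and 22 of the 24 at 48 h (median log2 ratio 1.49, percentile 100). Among them were the oxidase gene Cybb (94.1-fold, 56.3 to 169.9) and the inhibitory receptor gene Pirb (15.2-fold, 10.8 to 22.0). Monocyte and macrophage genes were higher for 10 of the 11 at 24 h and 13 of the 14 at 48 h (median log2 ratio 1.92, percentile 100), with the lipopolysaccharide co-receptor gene Cd14 at 24.2-fold (18.7 to 31.6) and Ms4a6c at 14.1-fold (10.6 to 19.1). Of the transcription factors of myeloid maturation, 17 of the 20 measured were higher at 24 h and 19 of the 22 at 48 h (median log2 ratio 1.58, percentile 100), among them Klf2 (17.9-fold, 13.6 to 23.9), Egr1 (15.8-fold, 13.03 to 19.3) and Klf6 (9.91-fold, 8.52 to 11.5). That list also holds factors not confined to myeloid cells, including Egr1, Klf2, Klf6, Fos and Jun. Its counts thus do not stand for maturation regulators alone. Spi1, which encodes the myeloid master regulator PU.1, stood at 187, 178, 186, 617 and 694 CPM at 0, 6, 12, 24 and 48 h. Cebpe, a regulator of secondary granule genes, stood at 126, 58.9, 65.2, 704 and 659 CPM. Genes listed as primary granule genes of promyelocytes were higher for 9 of the 14 and lower for 2 at 48 h (median log2 ratio 0.86, percentile 100), with the elastase gene Elane at 7.04-fold (6.47 to 7.67) and the myeloperoxidase gene Mpo at 1712 against 931 CPM, 1.84-fold, 1.79 to 1.89. The list member with the largest ratio, Hdc at 12.5-fold (10.6 to 14.7), encodes the enzyme histidine decarboxylase and not a granule protein.

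Progenitor genes went both ways with brequinar. At 24 h 9 of the 21 measured were higher and 1 lower (median log2 ratio 0.41, percentile 93.6), and 2 were higher and 5 lower at 48 h (median log2 ratio -0.09, percentile 24.4). Cd34, a surface marker of progenitors, stood at 141, 337, 412, 362 and 102 CPM over 0, 6, 12, 24 and 48 h. Meis1, a homeobox cofactor of HOXA9, stood at 41.6, 79.0, 93.9, 64.2 and 38.8 CPM. The zinc finger gene Ikzf2 was 5.65-fold (5.10 to 6.27) higher at 24 h. Flt3, a receptor tyrosine kinase of progenitors, was 2.78-fold (2.38 to 3.27) lower at 48 h. Kit, the stem cell factor receptor gene, stood at 99.9 against 121 CPM, 0.823-fold, 0.748 to 0.905, Hoxa9 at 98.2 against 75.9 CPM, 1.29-fold, 1.17 to 1.43 and Myc at 256 against 219 CPM, 1.17-fold, 1.10 to 1.246 at 48 h.

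Genes of growth were lower with brequinar at 24 and 48 h. Ribosome biogenesis genes were lower for 29 of the 36 at 24 h and 21 of the 36 at 48 h (median log2 ratio -0.64, percentile 0). Those lowest at 48 h were Utp20 (3.25-fold, 2.46 to 4.37), Npm1 (3.01-fold, 2.93 to 3.08) and Rrp9 (2.62-fold, 2.18 to 3.17), which encode nucleolar proteins. Ribosomal protein genes were lower for 22 of the 38 at 48 h (median log2 ratio -0.61, percentile 0.02), led by Rps7 (2.36-fold, 1.88 to 2.99) and Rplp0 (2.08-fold, 2.04 to 2.12). Purine synthesis genes were lower for 13 of the 22 and higher for 2 at 48 h (median log2 ratio -0.69, percentile 0), with Adsl, adenylosuccinate lyase, 2.54-fold (2.15 to 3.01) and Pfas 2.36-fold (2.15 to 2.59) lower. Pyrimidine metabolism genes were lower for 10 of the 21 and higher for 4 (median log2 ratio -0.53, percentile 0.08), with the deaminase gene Dctd 3.36-fold (2.75 to 4.15) lower and the dNTP hydrolase gene Samhd1 3.34-fold (2.85 to 3.90) higher. Dhodh, the gene of the inhibited enzyme, was 11.8 against 25.5 CPM, 2.16-fold lower, 1.65 to 2.86, Cad, the first enzyme of the pathway, 25.4 against 48.0 CPM, 1.89-fold lower, 1.58 to 2.28. Umps, the last, was 140.0 against 197 CPM, 1.41-fold lower, 1.303 to 1.53.

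Stress response genes were higher early with brequinar, and cell cycle genes parted later. Targets of ATF4, the transcription factor of the amino acid response, were higher for 16 of the 23 measured at 6 h (median log2 ratio 0.63, percentile 100) and lower for 17 of the 22 at 24 h (median log2 ratio -1.06, percentile 0). At 24 h the asparagine synthetase gene Asns was 4.77-fold (4.32 to 5.27) and Trib3 4.47-fold (3.64 to 5.53) lower. Targets of p53 were higher for 5 of the 12 at 6 h (median log2 ratio 0.36, percentile 99.1) and 5 of the 10 at 48 h (median log2 ratio 0.75, percentile 99.6), with the ribonucleotide reductase subunit gene Rrm2b 5.16-fold (4.44 to 6.02) higher at 6 h and the death receptor gene Fas 17.3-fold (12.7 to 24.0) higher at 48 h. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 53.3 against 21.7 CPM, 2.46-fold, 2.11 to 2.86. Replication stress and repair genes were higher for 5 of the 26 at 12 h (median log2 ratio 0.32, percentile 99.5), led by Brca1 (2.09-fold, 1.83 to 2.39) and Clspn (2.04-fold, 1.90 to 2.19), 2 genes of fork protection. They were lower for 6 of the 27 at 48 h (median log2 ratio -0.21, percentile 3.30). S phase genes were higher for 6 of the 40 at 12 h (median log2 ratio 0.34, percentile 100), led by the cyclin gene Ccne2 (2.51-fold, 2.15 to 2.94) and the helicase gene Brip1 (2.23-fold, 1.99 to 2.51), and lower for 14 of the 39 at 48 h (median log2 ratio -0.45, percentile 0), led by Ung, the thymidylate synthase gene Tyms (3.25-fold, 3.02 to 3.50) and the histone chaperone gene Nasp (2.84-fold, 2.60 to 3.10). Pcna, the sliding clamp of replication, was 55.8 against 111 CPM, 2.00-fold lower, 1.77 to 2.26. G2/M genes were higher for 21 of the 53 at 24 h (median log2 ratio 0.45, percentile 99.98) and 17 of the 52 at 48 h (median log2 ratio 0.39, percentile 99.99), led at 24 h by the spindle protein genes Nusap1 (3.07-fold, 2.89 to 3.27) and Gas2l3 (2.51-fold, 2.27 to 2.78). The proliferation marker gene Mki67 stood at 221 against 119 CPM, 1.85-fold, 1.72 to 1.99. At 2-fold the G2/M members higher numbered 3 at 24 h and 5 at 48 h. With cells weighted to the 0 h phase shares 9 were higher at 24 h. The phase classes were called from the S phase and G2/M lists, so this weighting removes part of their change by construction. The S phase members lower at 48 h numbered 4 with that weighting and 7 at 2-fold. Higher ATF4 and p53 targets were not particular to brequinar. At 6 h of withdrawal 14 of the 24 measured ATF4 targets were higher. The p53 target median at 12 h was 0.35 with brequinar and 0.29 with withdrawal, and it was 0.15 at 24 h of withdrawal. Each of these medians changed sign under an alternative setting. At 6 h of withdrawal Rrm2b was 5.15-fold (4.41 to 6.04) higher.

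**Figure D1:**
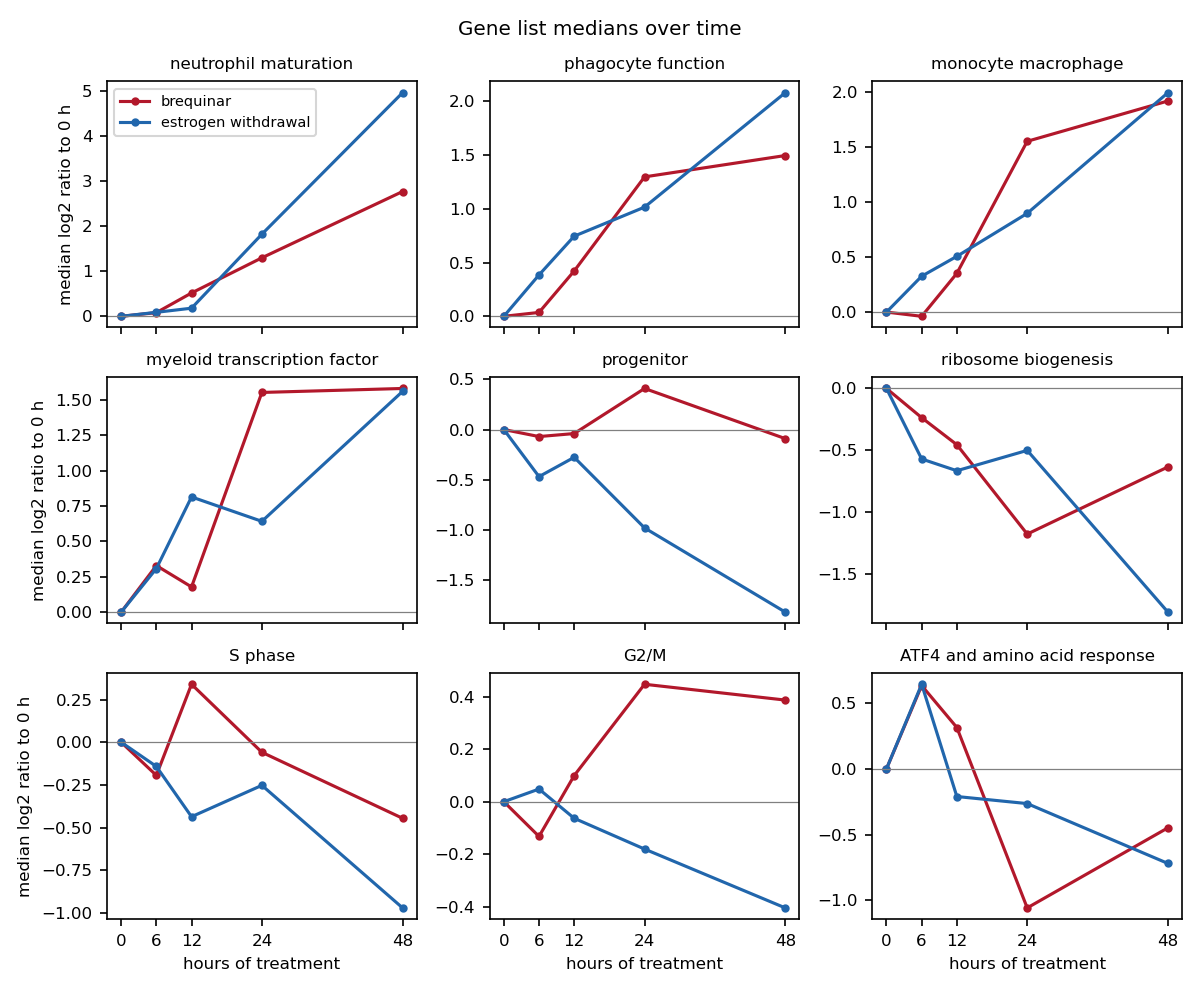
Each panel plots the median log2 ratio to 0 h of the measured members of 1 gene list (y axis) against hours of treatment (x axis) for brequinar (red) and estrogen withdrawal (blue), with 1 culture per point and no error bars. The progenitor list stands at -0.07 with brequinar and -0.47 with withdrawal at 6 h and at 0.41 and -0.98 at 24 h, and the neutrophil maturation list reaches 2.78 and 4.97 at 48 h.

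Withdrawal of beta-estradiol was compared with its own 0 h culture to show what the cells express once the hormone is removed. The genes ranked highest at 48 h included genes of maturing neutrophils. S100a8, which encodes a subunit of calprotectin, stood at 19979.6 against 72.2 CPM, 277-fold, 262 to 292, and Chil3, a chitinase-like protein of myeloid cells, at 8078 against 28.1 CPM, 287-fold, 263 to 314. Lcn2, the iron-scavenging lipocalin of granules (6548 against 167 CPM, 39.2-fold, 37.8 to 40.7), Cybb (216 against 2.25 CPM, 95.9-fold, 70.6 to 134), Hp (1865 against 45.9 CPM, 40.6-fold, 37.9 to 43.6) and Wfdc21 (516 against 4.56 CPM, 113-fold, 91.1 to 142) were higher too. The stefin genes BC100530 (6717 against 40.7 CPM, 165-fold, 153 to 177) and Stfa1 (15828 against 133 CPM, 119-fold, 114 to 123), Clec4a2 (85.4-fold, 73.3 to 100.0) and the glutathione transferase gene Mgst1 (64.1-fold, 55.9 to 74.0) were the others of the highest 10. How much of the 0 h counts of such genes is free RNA is not known. Barcodes of 2 to 100 UMIs held S100a8 at 1263 CPM and Chil3 at 543 CPM. With 5% of each sum removed in that profile, chosen after seeing the data, the ratios were 2209-fold and 8009-fold, and 431-fold for BC100530, 270-fold for Stfa1, 213-fold for Clec4a2 and 241-fold for Wfdc21, so their size is uncertain well beyond the counting interval. Itgam had 1 count at 0 h and 58 at 48 h (157-fold, 27.2 to 6324).

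The lowest genes at 48 h of withdrawal included transcription factors of progenitors and of B lineage cells. Ebf1, a B lineage factor, was 17.8 against 426 CPM, 24.0-fold lower, 20.0 to 28.9, Sox4 9.33 against 140.1 CPM, 15.0-fold lower, 11.7 to 19.6 and Hmga2 9.91 against 129 CPM, 13.02-fold lower, 10.2 to 16.8. Igll1, the surrogate light chain of B cell precursors (3.50 against 88.5 CPM, 25.3-fold lower, 17.0 to 39.6), the growth factor gene Angpt1 (3.79 against 70.8 CPM, 18.7-fold lower, 12.7 to 28.7) and the carbonic anhydrase gene Car2 (11.2 against 194 CPM, 17.3-fold lower, 13.8 to 22.0) were lower as well. The neuronal genes Nrgn and Nefh were 14.5-fold (13.2 to 16.1) and 18.7-fold (12.7 to 28.7) lower, Fabp5 was 11.7-fold (9.94 to 13.7) lower and Aebp1 94.1-fold (36.7 to 346) lower. With free RNA removed as above the ratio of Igll1 to 0 h was 0.00399, that of Nefh 0.0207, of Ebf1 0.0212, of Angpt1 0.0255, of Car2 0.0290, of Nrgn 0.0318 and of Aebp1 0. Those of Sox4, Hmga2 and Fabp5 were 0.0421, 0.0551 and 0.0603, so the folds of such low genes are uncertain beyond their intervals. At both 24 and 48 h, 224 genes were at least 2-fold higher and 66 at least 2-fold lower.

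With withdrawal all 25 measured neutrophil maturation genes were higher at 48 h (median log2 ratio 4.97, percentile 100). They include S100a9 (241-fold, 229.7 to 254), the partner of S100a8 in calprotectin. Phagocyte function genes were higher for 28 of the 29 (median log2 ratio 2.08, percentile 100), led by the actin-binding protein gene Lsp1, with 2 counts at 0 h (289-fold, 79.0 to 2402), Cybb and the Fc receptor gene Fcgr4 (93.6-fold, 46.9 to 219). Monocyte and macrophage genes were higher for 13 of the 14 (median log2 ratio 1.99, percentile 100), with the macrophage growth factor receptor gene Csf1r at 102-fold (54.7 to 214) and Cd14 at 49.1-fold (38.4 to 63.6). The chemokine receptor gene Ccr2 was the lower one (41.1 against 92.5 CPM, 2.25-fold lower, 1.98 to 2.56), a gene singled out after its value was seen. Transcription factors of myeloid maturation were higher for 18 of the 22 and lower for 3 (median log2 ratio 1.56, percentile 100), with Id2 at 44.3-fold (36.4 to 54.4) and Klf2 at 34.8-fold (27.2 to 45.2). Spi1 stood at 198, 246, 383, 497 and 755 CPM and Cebpe at 116, 98.1, 232, 755 and 612 CPM over 0, 6, 12, 24 and 48 h. Primary granule genes were higher for 8 of the 14 at 24 h (median log2 ratio 0.73, percentile 100), when Mpo reached 2859 CPM from 941 CPM at 0 h. At 48 h 5 of them were higher and 6 lower (median log2 ratio -0.31, percentile 44.3), and Mpo stood at 503 CPM.

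With withdrawal 9 of the 19 progenitor genes were lower at 6 h and 3 higher (median log2 ratio -0.47, percentile 0). They were lower for 11 of the 18 at 24 h (median log2 ratio -0.98, percentile 0) and 16 of the 18 at 48 h (median log2 ratio -1.82, percentile 0), led at 48 h by Angpt1, Sox4 and Flt3 (14.2-fold, 10.5 to 19.7). Cd34 was 12.4 against 138 CPM, 11.1-fold lower, 8.95 to 14.0, Meis1 6.70 against 42.1 CPM, 6.29-fold lower, 4.67 to 8.66, Kit 21.9 against 121 CPM, 5.52-fold lower, 4.68 to 6.56 and Myc 70.4 against 214 CPM, 3.04-fold lower, 2.77 to 3.35 at 48 h. Cd93 (4.06-fold, 3.53 to 4.68) and Hoxa9 (150.2 against 78.4 CPM, 1.92-fold, 1.77 to 2.08) were the members on the higher side. All 36 ribosome biogenesis genes were lower (median log2 ratio -1.81, percentile 0), as were 19 of the 23 purine synthesis genes (median log2 ratio -1.39, percentile 0), 15 of the 21 pyrimidine metabolism genes (median log2 ratio -1.26, percentile 0), 34 of the 38 S phase genes (median log2 ratio -0.97, percentile 0), 20 of the 25 replication stress and repair genes (median log2 ratio -0.91, percentile 0.26) and 18 of the 52 G2/M genes (median log2 ratio -0.40, percentile 44.5). Examples are the nucleolar gene Utp20 (7.18-fold, 5.04 to 10.6), the purine enzyme gene Ppat (5.24-fold, 4.58 to 6.02), Dctd (7.68-fold, 5.91 to 10.2), Ung (4.90-fold, 4.00 to 6.05), the exonuclease gene Exo1 (3.95-fold, 3.02 to 5.26), the checkpoint gene Rad1 (4.94-fold, 3.74 to 6.66), the checkpoint kinase gene Chek1 (4.52-fold, 3.55 to 5.84) and the heterochromatin protein gene Cbx5 (2.85-fold, 2.61 to 3.10). Dhodh was 3.68-fold (2.71 to 5.12) lower, Cad 4.75-fold (3.72 to 6.16), Umps 3.60-fold (3.24 to 4.01) and Pcna 1.98-fold (1.77 to 2.21) lower, while the ratios were 1.09-fold (1.01 to 1.18) for Mki67 and 1.08-fold (0.879 to 1.31) for Cdkn1a. Esr1, the estrogen receptor gene, stood at 8.16 against 3.65 CPM, 2.24-fold, 1.54 to 3.23. Estrogen receptor target genes were higher for 2 and lower for 3 of 5 (median log2 ratio -1.51, percentile 0.93), and with brequinar for 2 and 1 of 5 (median log2 ratio 0.22, percentile 76.5), where Esr1 stood at 11.6 against 4.87 CPM, 2.39-fold, 1.71 to 3.33.

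Stefin genes such as Stfa1 and BC100530 are near-identical copies, so how their counts divide is uncertain. Median-of-ratios scaling moved the 48 h withdrawal culture by 0.33 on the log2 scale against CPM and the 24 h brequinar culture by -0.11. Under it 22 S phase genes and 4 G2/M genes were lower at 48 h of withdrawal and the primary granule and apoptosis medians turned to 0.04 and 0.06. Weighted to the 0 h phase shares, 11 S phase and 3 G2/M genes were lower, and the G2/M median turned to 0.19. The classes were called from these same lists, so the weighting removes part of their change by construction.

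**Figure D2:**
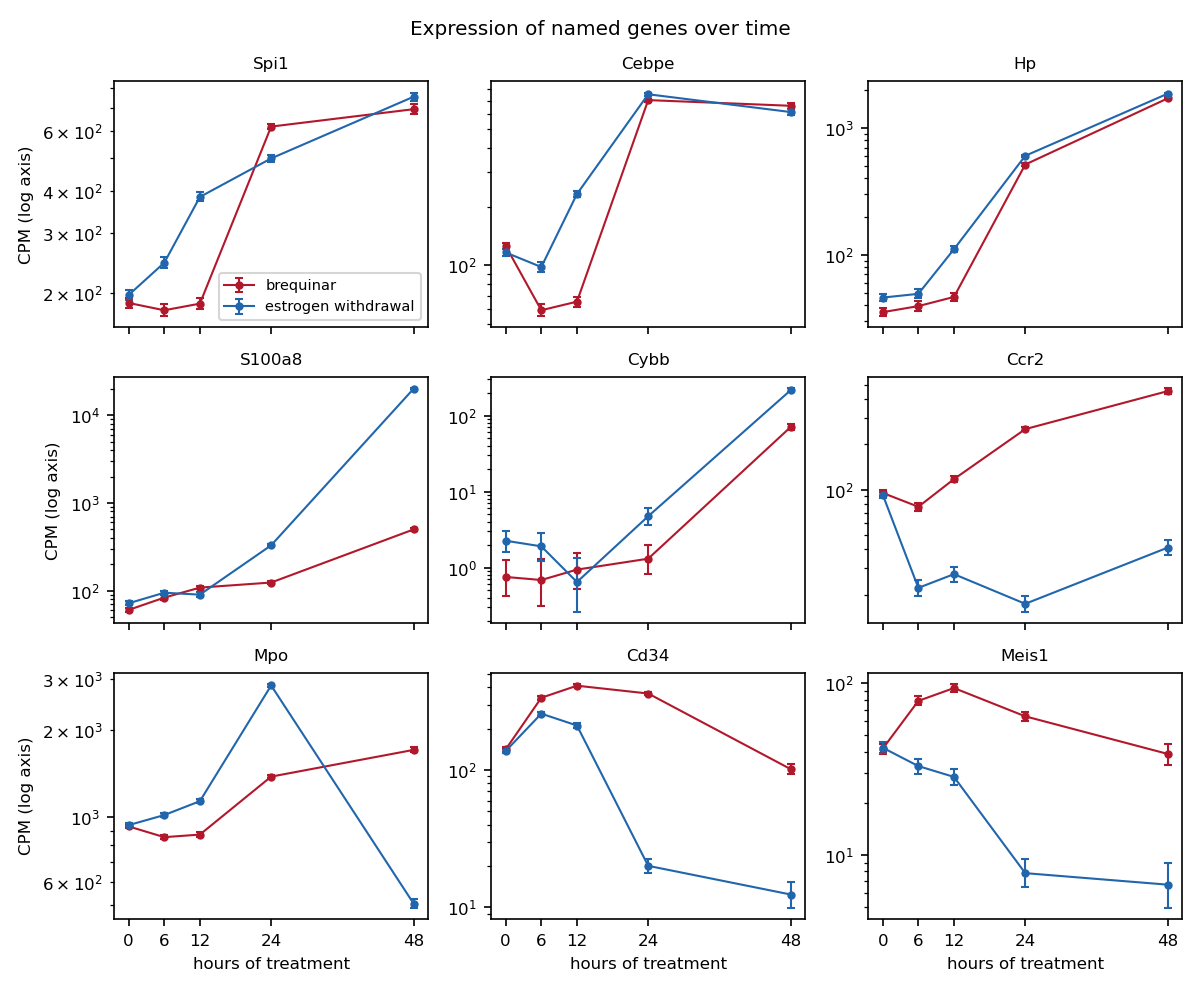
Expression in CPM (log y axis) is plotted against hours of treatment (x axis) for 9 genes, with brequinar in red and estrogen withdrawal in blue; points are single cultures and bars are exact 95% Poisson intervals of the counts. Spi1 and Cebpe reach 694 and 659 CPM with brequinar and 755 and 612 CPM with withdrawal at 48 h, whereas Cd34 stands at 102 and 12.4 CPM.

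At 6 h the treatments were compared to ask how far the earliest differences are shared. Nupr1, a stress-induced target of ATF4, was highest in both, at 169 against 8.08 CPM, 20.9-fold, 17.8 to 24.6 with brequinar and 143 against 8.75 CPM, 16.4-fold, 14.0 to 19.4 with withdrawal. With free RNA removed as above the Nupr1 ratios were 32.5-fold and 24.4-fold. Trib3, another ATF4 target, was 5.33-fold (4.86 to 5.85) and 6.88-fold (6.23 to 7.62) higher. With brequinar the small nucleolar RNA host genes Snhg12 (6.27-fold, 5.85 to 6.73) and Snhg1 (4.48-fold, 4.37 to 4.59) and Mamdc2 (11.1-fold, 9.11 to 13.5) followed. With withdrawal the fatty acid receptor gene Ffar2 (8.38-fold, 7.36 to 9.58), the long noncoding RNA gene Neat1 (6.69-fold, 6.30 to 7.11) and Rrm2b (5.15-fold, 4.41 to 6.04) did. Rgcc, a cell cycle regulator, was 3.03-fold (2.86 to 3.21) and 4.35-fold (4.07 to 4.66) lower. Igll1 (3.53-fold, 3.15 to 3.97), the chaperone gene Hspa8 (3.12-fold, 2.95 to 3.30), Ms4a3 (2.97-fold, 2.82 to 3.14) and the foldase gene Fkbp11 (2.71-fold, 2.48 to 2.96) were the other lowest genes with brequinar. Ebf1 (11.6-fold, 10.5 to 12.7), the progenitor factor gene Hlf (10.0-fold, 8.78 to 11.5), Angpt1 (6.29-fold, 5.27 to 7.56) and Myc (4.37-fold, 4.01 to 4.77) were those with withdrawal. ATF4 targets were higher for 14 of the 24 measured with withdrawal (median log2 ratio 0.64, percentile 100). Among 6866 genes at 20 CPM or more in any condition, 539 were at least 1.5-fold higher in both (714 with brequinar and 982 with withdrawal, which independent lists would share in 102), and 234 were lower in both (350 and 542, 27.6 if independent). The log2 ratios of the treatments, each against its own 0 h culture, correlated across genes with Pearson r of 0.83, 0.48, 0.52 and 0.78 at 6, 12, 24 and 48 h, and Spearman rho of 0.83, 0.50, 0.53 and 0.76. Simulated unchanged cultures gave r of 0.00204, -0.00465, 0.00445 and 0.00353. The observed covariances were 0.136, 0.0931, 0.203 and 0.695 against simulated ones of 1.1e-05, -2.48e-05, 2.12e-05 and 3.18e-05. Genes are not independent replicates, so these values describe the cultures.

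The treatments were set against each other at matched times to show where they part. At 48 h brequinar cells held less of some genes of maturing neutrophils than withdrawal cells. Camp, the cathelicidin gene (5.54 against 859 CPM, 155-fold lower, 108 to 232), Ltf, the lactoferrin gene (7.07 against 493 CPM, 69.8-fold lower, 50.5 to 99.3), Ngp (42.0 against 2570.0 CPM, 61.2-fold lower, 53.6 to 70.2), S100a9 (421 against 20183 CPM, 47.9-fold lower, 45.9 to 50.0) and S100a8 (499.9 against 19979.6 CPM, 40.0-fold lower, 38.4 to 41.6) were the lowest 5. With free RNA removed as above the ratio of Camp was 0.00314 and that of Sdc1 35.6-fold. Brequinar cells held more of Csrp3 (25.6-fold, 18.5 to 36.5), the proteoglycan gene Sdc1 (350.4 against 16.2 CPM, 21.7-fold, 17.9 to 26.5), the interferon-induced membrane protein gene Ifitm1 (3883 against 277 CPM, 14.0-fold, 13.4 to 14.7), the mast cell carboxypeptidase gene Cpa3 (3131 against 266 CPM, 11.8-fold, 11.2 to 12.4) and Ccr2 (452 against 41.1 CPM, 11.0-fold, 9.72 to 12.5). By list, 10 of the 19 progenitor genes were higher with brequinar at 6 h and 2 lower (median log2 ratio 0.59, percentile 100). The 6 h medians were -0.29 for neutrophil maturation, -0.31 for transcription factors of myeloid maturation and -0.30 for G2/M genes, each at percentile 0. At 12 h 10 of the 22 phagocyte function genes (median log2 ratio -0.55, percentile 0) and 3 of 7 monocyte and macrophage genes were lower with brequinar (median log2 ratio -0.49, percentile 0.24). Higher at 12 h were 31 of the 40 S phase genes (median log2 ratio 0.73, percentile 100) and 17 of the 18 cholesterol synthesis genes (median log2 ratio 1.01, percentile 100). At 24 h 9 of 14 neutrophil maturation genes (median log2 ratio -0.79, percentile 0) and 20 of the 33 ribosome biogenesis genes were lower with brequinar (median log2 ratio -0.72, percentile 0). At that time 11 of the 22 phagocyte function genes were higher and 2 lower (median log2 ratio 0.53, percentile 99.92), as were 8 and 1 of 12 monocyte and macrophage genes (median log2 ratio 1.13, percentile 100). Higher at 24 h were also 17 of the 20 progenitor genes (median log2 ratio 1.49, percentile 100), 31 of the 53 G2/M genes (median log2 ratio 0.64, percentile 100) and 10 of the 39 S phase genes (median log2 ratio 0.32, percentile 91.5). At 48 h 23 of the 25 neutrophil maturation genes were lower with brequinar (median log2 ratio -3.27, percentile 0) and 17 of the 29 phagocyte function genes (median log2 ratio -0.71, percentile 0), whereas 18 of the 20 progenitor genes were higher (median log2 ratio 1.77, percentile 100), among them Angpt1 (15.7-fold, 10.5 to 24.5) and Cd34 (8.20-fold, 6.51 to 10.4). Higher with brequinar, too, were 40 of the 52 G2/M genes (median log2 ratio 0.79, percentile 100), 20 of the 36 S phase genes (median log2 ratio 0.59, percentile 98.7) and 31 of the 33 ribosome biogenesis genes (median log2 ratio 1.18, percentile 100). Primary granule genes were higher for 8 of the 14 and lower for 1 (median log2 ratio 0.84, percentile 99.99), and 12 of the 37 ribosomal protein genes were lower (median log2 ratio -0.44, percentile 0.01). Of the monocyte and macrophage genes at 48 h 3 were higher and 4 lower of 15 (median log2 ratio -0.21, percentile 0.31). The median over all genes of this 48 h comparison was 0.34. Under median-of-ratios scaling, chosen for it after seeing the data, 10 of 36 S phase genes were higher (median 0.30), 22 of 52 G2/M genes (0.47), 26 of 33 ribosome biogenesis genes (0.85) and 18 of 20 progenitor genes (1.49), and 7 of 15 monocyte and macrophage genes were lower (-0.56). At 24 h the median over all genes was 0.23. That scaling then gave 8 of 39 S phase (0.17), 22 of 52 G2/M (0.48) and 10 of 22 phagocyte function genes (0.37) higher. It gave 26 of 33 ribosome biogenesis genes (-0.87) lower. Without the 11 cells named above, S100a8, S100a9, Ngp, Camp, Chil3 and Lcn2 summed to 617 CPM in the 48 h brequinar culture, against 251 CPM in such cells of its 0 h culture. Barcodes of 2 to 100 UMIs, a measure of free RNA, held S100a8 at 1263 CPM and Prg2 at 3139 CPM. Cells with at least 10% mitochondrial UMIs made up 18.4% of the brequinar 0 h culture and 1.70% of the 48 h one (16.6% and 3.12% for withdrawal).

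Cell cycle phase was scored because the series title places the response in S phase. Classes are ranges of a score and not types, scores read free RNA as well, and no cycling is read from them. In cells thinned to 2500 UMIs, the S class held 36.9% (34.3 to 39.6), 26.4% (23.9 to 29.1), 39.7% (37.0 to 42.3), 10.6% (9.06 to 12.3) and 5.63% (3.80 to 7.99) at 0, 6, 12, 24 and 48 h of brequinar. The G2/M class held 58.6% (55.9 to 61.3), 44.9% (41.9 to 47.8), 55.6% (52.9 to 58.3), 86.7% (84.8 to 88.4) and 74.6% (70.6 to 78.3), and the G1-like class, with neither score above 0, 4.51%, 28.7%, 4.76%, 2.72% and 19.8%. With withdrawal the S class held 35.2% (32.5 to 38.0), 24.5% (22.0 to 27.2), 19.8% (17.4 to 22.4), 29.2% (26.6 to 31.9) and 7.77% (6.10 to 9.73). Its G2/M class held 60.0%, 51.7%, 45.9%, 50.1% and 30.5%, and its G1-like class 4.77% (3.63 to 6.16), 23.8% (21.2 to 26.5), 34.2% (31.3 to 37.3), 20.7% (18.4 to 23.2) and 61.7% (58.4 to 64.9). Unthinned, the S class held 47.0%, 36.4%, 49.9%, 12.0% and 6.06% with brequinar and 46.1%, 31.2%, 22.7%, 34.9% and 8.72% with withdrawal. The unthinned G2/M class held 49.1%, 40.3%, 46.8%, 85.4% and 73.7% with brequinar, and the G1-like class 3.10%, 20.7%, 33.1%, 18.5% and 60.5% with withdrawal. Thinning left out 194, 145, 212, 97 and 13 cells of the brequinar series and 180, 196, 230, 249 and 75 of the withdrawal series, in order of time. Cells within 0.05 of a boundary made up 4.27% (brequinar 48 h) to 18.2% (brequinar 12 h) of a condition. With both boundaries at the 75th percentile of the 0 h cells, the G2/M class held 24.1%, 14.7%, 11.9%, 45.6% and 53.2% over the times of brequinar and 24.98%, 27.1%, 28.4%, 23.7% and 19.5% over those of withdrawal. The G1-like class then held 51.3%, 68.1%, 50.3%, 41.9% and 41.7% with brequinar and 52.4%, 56.9%, 58.1%, 55.2% and 73.6% with withdrawal. The S class of brequinar then held 24.7% (22.4 to 27.1), 17.2%, 37.8% (35.1 to 40.4), 12.6% and 5.05%. The direction of the G1-like share with brequinar and of the early G2/M share with withdrawal thus depends on the boundary. So does the S class share at 12 h of brequinar against 0 h, whose intervals overlapped with the boundary at 0.

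**Figure D3:**
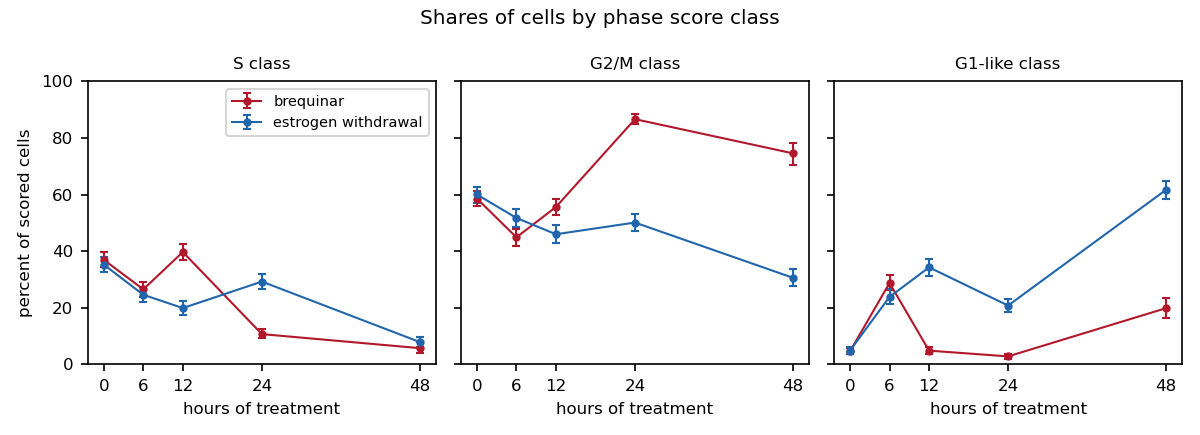
The percent of scored cells in the S, G2/M and G1-like classes (y axis) is plotted against hours of treatment (x axis) for brequinar (red) and estrogen withdrawal (blue), with points for single cultures thinned to 2500 UMIs per cell and bars for exact 95% binomial intervals. At 24 h of brequinar the G2/M class stands at 86.7% and the S class at 10.6%, and at 48 h of withdrawal the G1-like class at 61.7%.

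Maturation genes were then compared within each class, to ask whether they were higher in S class cells themselves. At 24 h of brequinar 152 S class cells stood against 483 S class cells at 0 h. In them 19 of 22 phagocyte function genes were higher (median log2 ratio 1.13), 9 of 10 monocyte and macrophage genes (1.72), 13 of 19 transcription factors of myeloid maturation (0.91) and 8 of 12 neutrophil maturation genes (1.39), each at percentile 100. Among cells whose leading phase score exceeded the next by more than 0.1, the neutrophil maturation genes higher numbered 5. Spi1 stood in the S class at 457 against 189 CPM, 2.41-fold, 2.20 to 2.64, Cebpe at 346 against 119.9 CPM, 2.89-fold, 2.59 to 3.21 and Hp at 593 against 32.3 CPM, 18.4-fold, 15.9 to 21.4. In the G2/M class, with 1242 cells against 767, Spi1 stood at 641 against 185 CPM, 3.46-fold, 3.30 to 3.63 and Cebpe at 759 against 127 CPM, 5.99-fold, 5.67 to 6.32, and 19 of 22 phagocyte function genes were higher (median 1.29). The G1-like class held 39 cells against 59, with 18 of 22 phagocyte function genes higher (median 1.297) but 4 of 11 neutrophil maturation genes higher and 3 lower (median 0.48, percentile 94.1). In the G2/M class 10 of 12 neutrophil maturation genes were higher. Within the S class the S phase genes had a median of 0.18 and the G2/M genes one of 0.54 at 24 h, and the class held 29 cells at 48 h. With withdrawal at 24 h (334 against 413 S class cells) 13 of 21 phagocyte function genes (median 0.87) and 9 of 10 neutrophil maturation genes (median 1.73) were higher in the S class, and 11 of 18 progenitor genes were lower (median -0.90). Of 8 monocyte and macrophage genes there, 4 were higher and 3 lower (median 0.61).

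**Figure D4:**
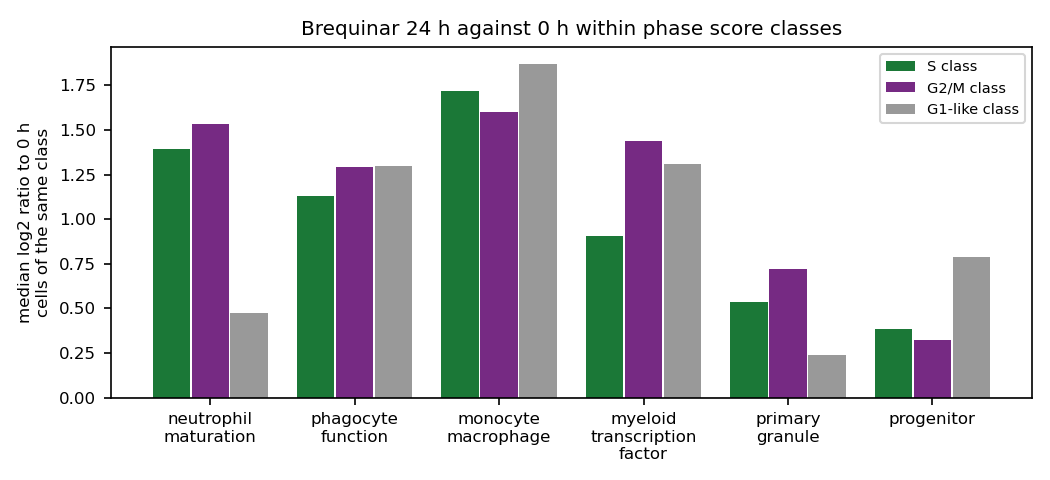
Bars give the median log2 ratio of the measured members of 6 gene lists (x axis) between brequinar 24 h cells and 0 h cells of the same phase score class (y axis), in the S (green), G2/M (purple) and G1-like (grey) classes, with 1 culture per condition and no error bars. The phagocyte function bars stand at 1.13, 1.29 and 1.297.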

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

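The tests of counting noise, the share of cells rich in mitochondrial RNA, handling, free RNA, and depth or scaling, the last at 24 h included, were chosen only after the result was seen. Medians of lists with 5 or more measured members in each treatment are given as values where they had opposite signs and both lay beyond 0.13, the 95th percentile of genes between the 0 h cultures. The difference was not tested, since each condition is 1 culture. At 12 h the S phase median was 0.34 with brequinar and -0.44 with withdrawal. The ATF4 and amino acid response median was 0.31 and -0.21 at 12 h. Replication stress and repair stood at 0.32 and -0.27, and cholesterol synthesis at 0.59 and -0.40, also at 12 h. The withdrawal medians at 12 h turned to 0.0190 for replication stress and repair with cells weighted to the 0 h phase shares, and to 0.14 for cholesterol synthesis with members at 100 CPM or more. At 24 h the progenitor median was 0.41 with brequinar and -0.98 with withdrawal, and the G2/M median 0.45 and -0.18, the latter at percentile 31.2 and beside a median of -0.14 over all genes, so it does not stand apart from the shift of that culture. At 48 h the medians were 0.86 and -0.31 for primary granule genes, 0.39 and -0.40 for G2/M, 0.13 and -0.25 for apoptosis, and 0.22 and -1.51 for estrogen receptor targets. At 48 h of withdrawal the median over all genes was -0.33, and the primary granule, G2/M and apoptosis medians lay at percentile 44.3, 44.5 and 57.7 of random lists, so these 3 signs do not stand apart from the shift of that culture. They turned to 0.0430 and 0.0603 for primary granule and apoptosis genes with median-of-ratios scaling and to 0.19 for G2/M genes with phase weighting. The latter is in part by construction, since the phase classes were called from the G2/M list itself. The unspliced matrix, which entered no comparison, held 107485183 UMIs, 33.9% of all UMIs.

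Both treatments shared much of their 6 h difference from 0 h (r = 0.829 across 6866 genes). Counting noise is argued against by the simulated r of 0.00204, and a larger share of cells with at least 10% mitochondrial UMIs by their share of UMIs at 6 h of brequinar, 1.05 (0.866 to 1.26) times that of 0 h, although it was 2.08 (1.68 to 2.53) times with withdrawal. A change of expression within such shallow cells cannot be told apart, since the r of 0.829 without them decides nothing when they hold at most 5.68% of the UMIs. Handling or time in culture common to both series cannot be told apart from a response to the treatments, because no vehicle culture at 6 h was used here, and a shared biological response to the drug and to hormone removal stays open, untested. Of the 6 h median change of the shared genes, 103% was left at 24 h with brequinar and 33.3% with withdrawal, where the median was 0.77, 0.62, 0.26 and 0.75 at 6, 12, 24 and 48 h, so these values favour neither a passing effect nor a lasting one.

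Genes of maturing neutrophils such as S100a8 were higher in the 48 h brequinar culture, where 66.9% of the UMIs of the 6 genes lay in 11 cells, which argues against free RNA as the source of that part and leaves it open for the remainder. Doublets of a brequinar and a withdrawal cell are argued against by the median UMIs of those 11 cells, 0.812 (0.606 to 1.06) of that of the other cells of the culture. Cells of the 48 h withdrawal culture called as brequinar cannot be told apart from brequinar cells that matured further. Ifitm1, Cpa3, Sdc1 and Ccr2 were picked from the 5 genes highest with brequinar against withdrawal in these same 48 h cultures. A gap in their level between brequinar and withdrawal cells is therefore set by that choice. The 11 cells held them at a summed 1182 CPM, against 7930 CPM in the other brequinar cells and 433 CPM in withdrawal cells rich in the 6 genes. The value of the 11 cells lies 2.73-fold (2.22 to 3.33) above the latter. A wrong call could thus account for some of the 11 cells, which number 2.08% (1.04 to 3.70) of the culture.

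G2/M genes were higher with brequinar at 24 and 48 h, which depth or scaling alone does not account for, since the median was 0.35 at 24 h and 0.37 at 48 h with median-of-ratios scaling, and 0.52 and 0.314 in cells thinned to equal UMIs. Accumulation in mitosis may contribute. A list of mitotic genes written before its values were seen had a median of 0.55 at 24 h (9 higher and 0 lower of 18) and a list of S to G2 genes one of 0.16 (6 higher and 0 lower of 19), a difference of 0.388. The median over all genes at 24 h of brequinar was 0.16 as well, so the S to G2 list does not stand apart from it. Both lists share members with the G2/M list, and DNA content was not measured here. Slower passage through S or any later phase stays open and untested.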

How the results depend on the processing

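Chosen after seeing the data were the removal of the cells richest in S100a8 and related neutrophil genes, the subtraction of free RNA, lists within classes bounded at the 75th percentile, median-of-ratios scaling of brequinar against withdrawal, and the correlation in cells under 10% mitochondrial UMIs. Of the main counts and shares under an alternative, 276 stayed within 1.5 times or within their interval and 56 did not. Of the list medians, 1711 lay within the spread between the 0 h cultures, 291 moved by more and 24 changed sign, and of the named gene folds 364 lay within their interval, 186 outside it and 0 changed direction. Subtracting free RNA took 53 of 70 named gene folds outside their interval, the most of any setting, and moved 18 list medians. Within these limits stayed all main counts against 0 h with cells between the 5th and 95th percentile of UMIs, cells under 10% mitochondrial UMIs, the other 0 h culture, free RNA subtracted and the cells richest in these neutrophil genes removed.

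At a 2-fold threshold, brequinar members higher were 7 for ATF4 targets at 6 h, 4 for progenitor and 3 for G2/M at 24 h and 5 for G2/M at 48 h, and members lower at 48 h were 7 for S phase and 8 for ribosome biogenesis. With withdrawal, 6 ATF4 targets were higher at 6 h, and 20 S phase and 4 G2/M genes lower at 48 h. These counts are lower by construction.

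With members at 100 CPM or more, which leaves fewer genes, brequinar members higher at 24 h were 12 for phagocyte function, 6 for monocyte macrophage, 2 for progenitor, 9 for transcription factors and 9 for G2/M, and members lower 10 for ATF4 targets and 17 for ribosome biogenesis. At 48 h they were 4 monocyte macrophage, 12 transcription factor and 9 G2/M genes higher, and 2 progenitor and 9 S phase genes lower. For withdrawal they were 4 progenitor genes lower at 24 h, and at 48 h 8 monocyte macrophage and 10 transcription factor genes higher, and 7 progenitor, 17 S phase, 9 G2/M and 20 ribosome biogenesis genes lower. Medians that changed sign with brequinar were transcription factors -0.00660, p53 targets -0.0886 and apoptosis -0.0158 at 12 h and apoptosis -0.0141 at 24 h. With withdrawal they were apoptosis -0.0759 at 6 h, p53 targets -0.15 and cholesterol synthesis 0.14 at 12 h, estrogen receptor targets 0.46 at 24 h and apoptosis 0.0922 at 48 h. The correlations over genes at 100 CPM or more were 0.838, 0.573 and 0.804 at 6, 24 and 48 h.

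With no minimum beyond 1 count, which adds genes, members higher were 22 monocyte macrophage genes at 24 h and 27 neutrophil maturation and 22 monocyte macrophage genes at 48 h of brequinar, with 8 progenitor genes lower at 48 h. With withdrawal they were 22 ATF4 targets at 6 h and 21 monocyte macrophage genes at 48 h. Medians that changed sign were mast cell and basophil 0.92 at 24 h of brequinar, interferon response 0.0611 and estrogen receptor targets 0.0470 at 6 h of withdrawal, p53 targets -0.00111, interferon response 0.0217 and estrogen receptor targets 0.0250 at 24 h, and apoptosis 0.16 at 48 h.

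Weighted to the 0 h phase shares, 9 G2/M genes were higher at 24 h and 4 S phase genes lower at 48 h of brequinar, and 11 S phase and 3 G2/M genes lower at 48 h of withdrawal. Medians that changed sign were G2/M 0.0506 at 6 h and mast cell and basophil -1.20 at 48 h of brequinar, and replication stress and repair 0.0190 at 12 h and G2/M 0.19 at 48 h of withdrawal. Median-of-ratios scaling gave 22 S phase and 4 G2/M genes lower at 48 h of withdrawal and medians of 0.0430 for primary granule and 0.0603 for apoptosis genes, by its shift of 0.33 for that culture. For brequinar against withdrawal at 48 h it gave 10 S phase and 22 G2/M genes higher and 7 monocyte macrophage genes lower. The mean over cells gave 30 G2/M genes lower at 48 h of withdrawal and a mast cell and basophil median of -0.63 at 48 h of brequinar. Cells between the 5th and 95th percentile of UMIs gave that list a median of 1.03 at 24 h of brequinar.

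Unthinned, 34.9% of cells at 24 h of withdrawal lay in the S class and 46.6% in the G2/M class. With boundaries at the 75th percentile of the 0 h cells, the S class held 12.6% and the G2/M class 45.6% at 24 h and the latter 53.2% at 48 h of brequinar. The classes held 21.1% and 23.7% at 24 h and the G2/M class 19.5% at 48 h of withdrawal. With clear phases alone, 5 neutrophil maturation genes were higher in the S class at 24 h of brequinar. Beyond what fewer, more or rescaled genes set, the cause was not tested.

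Not run were spliced plus unspliced counts, since barcodes of the unspliced lines were not used here, each run alone, since the runs share 1 matrix, and the tests and left-out cultures planned for replicated cultures. No paired analysis was possible because each condition is 1 culture and the result comes from no test. Depth limits genes near the floor of 0.151 to 0.573 CPM. The 46% to 54% of genes recovered when simulated at 1.5-fold follow from a fold set at the threshold and measure no effect of depth.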

Other observations

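Some genes of other blood lineages were higher with brequinar. Il4, a cytokine of basophils and T cells (7 counts at 0 h), stood at 20.6 against 0.351 CPM, 58.7-fold, 27.5 to 149.5 at 48 h, and the mast cell carboxypeptidase gene Cpa3 at 3131 against 337 CPM, 9.28-fold, 9.02 to 9.55. Megakaryocyte genes were higher for 4 of 4 at 48 h (median log2 ratio 1.93, percentile 99.93), led by the integrin gene Itga2b (14.1-fold, 11.2 to 17.8) and Itgb3 (6.71-fold, 5.25 to 8.60). None of this list was measured at 48 h of withdrawal. Eosinophil genes were higher for 3 of 3 with brequinar (median log2 ratio 2.38, percentile 99.7). They were higher for 4 of 4 with withdrawal (median log2 ratio 1.99, percentile 99.4), including the peroxidase gene Epx (44.1-fold, 24.7 to 86.8) and Prg2 (7519 against 631 CPM, 11.9-fold, 11.7 to 12.2). In the mast cell and basophil list 2 genes were higher and 2 lower of 4 with brequinar at 48 h (median log2 ratio 0.73, percentile 88.2). The sign of that median is open, since it was -0.63 with the mean over cells and -1.20 weighted to the 0 h phase shares. With withdrawal 2 of 3 were lower (median log2 ratio -1.75, percentile 0.52), where Mcpt8 was 9.30-fold (6.81 to 13.04) and Il6 4.51-fold (3.54 to 5.83) lower. Of the erythroid list the factor gene Gata1 was 9.79-fold (7.71 to 12.6) and Blvrb 4.31-fold (3.75 to 4.96) higher at 24 h of brequinar (2 higher and 1 lower of 3, median log2 ratio 1.76, percentile 99.92). Car2 was lower in both treatments at 48 h, by 5.12-fold (4.43 to 5.94) with brequinar. Among lymphoid genes Cd79a was 8.78-fold (6.52 to 11.9) higher with brequinar and Ighm, the immunoglobulin heavy chain gene, 39.2-fold (28.4 to 55.4) higher with withdrawal, with 1 higher of 2 measured in each (median log2 ratio 1.19 and 1.79). Of 2 dendritic cell genes measured, 0 were higher and 0 lower at 48 h of brequinar (median log2 ratio 0.10) and 2 lower with withdrawal (-0.99), led by Tcf4 (2.69-fold, 2.01 to 3.69).

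Sterol and energy genes differed by time. At 6 h cholesterol synthesis genes were lower for 4 of the 16 with brequinar (median log2 ratio -0.29, percentile 0) and 5 of the 15 with withdrawal (median log2 ratio -0.39, percentile 0.01). They were higher for 13 of the 18 measured at 12 h of brequinar (median log2 ratio 0.59, percentile 100), led by the isomerase gene Idi1 (2.76-fold, 2.57 to 2.96) and Acat2 (2.55-fold, 2.32 to 2.81). They were higher for 14 of the 18 at 24 h of withdrawal (median log2 ratio 0.84, percentile 100), led by the farnesyl diphosphate synthase gene Fdps (3.91-fold, 3.55 to 4.31) and Sc5d (2.80-fold, 2.58 to 3.04). Glycolysis genes were lower for 4 of the 16 at 6 h (median log2 ratio -0.27, percentile 0.46) and 4 of the 16 at 12 h of brequinar (median log2 ratio -0.29, percentile 0.12). They were higher for 6 of the 16 at 48 h of brequinar (median log2 ratio 0.46, percentile 98.7), led by the phosphofructokinase gene Pfkl (2.41-fold, 2.12 to 2.75) and Pkm (1.92-fold, 1.86 to 1.99). The number was 8 of the 16 with withdrawal (median log2 ratio 0.58, percentile 99.6), led by the glucose transporter gene Slc2a3 (41.9-fold, 24.4 to 77.9) and Slc16a3 (3.52-fold, 3.14 to 3.94). Respiratory chain genes of the oxidative phosphorylation list were lower for 7 of the 23 with brequinar (median log2 ratio -0.37, percentile 9.27) and 14 of the 23 with withdrawal (median log2 ratio -0.78, percentile 5.34), led by Atp5b (1.98-fold, 1.90 to 2.06) and the cytochrome c gene Cycs (3.11-fold, 2.88 to 3.37). Apoptosis genes were higher for 4 of the 12 with brequinar (median log2 ratio 0.13, percentile 61.5), led by the p53 target gene Pmaip1 (4.51-fold, 3.85 to 5.29) and Apaf1 (1.95-fold, 1.55 to 2.45). With withdrawal 4 were higher and 2 lower (median log2 ratio -0.25, percentile 57.7), with the survival gene Bcl2 4.46-fold (3.49 to 5.77) and Bid 2.55-fold (2.27 to 2.87) lower. Interferon response genes were higher for 2 and lower for 1 of 4 with brequinar (median log2 ratio 0.34, percentile 81.3), with Trim30a at 2.12-fold (1.71 to 2.62) and Ifi35 at 1.63-fold (1.39 to 1.91). With withdrawal 1 was higher and 1 lower of 4 (median log2 ratio -0.10, percentile 64.0).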
